A study of Mus musculus with 12 samples.

How the data were processed

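RNA sequencing of mouse bone marrow-derived macrophages was analysed from gene tables of 12 libraries in 4 labelled groups of 3. Per the labels' protocols, marrow came from femurs and tibias, cells were grown with macrophage colony-stimulating factor in RPMI 1640 medium, and RNA was taken with TRIzol. The labels name both an Illumina TruSeq RNA preparation kit and a KAPA Stranded kit, so which kit made which library is open. The reads were placed on the mouse build mm10, per the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation are not given in the sources used here.

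The deposited count table holds whole-number read counts per gene that the authors had not normalized, for 54446 Ensembl gene identifiers. The second deposited table holds FPKM values that the authors computed, that is, fragments per kilobase of gene, scaled to libraries of equal total. The FPKM values were those counts scaled by each library's total, checked to within 0.0102%, so the tables are not independent measurements. Since it is not known whether strand was used in counting, values of genes that overlap or lie antisense to one another are uncertain. Values of genes with many near-identical pseudogenes are uncertain too. Gapdh is one, and it is left out of the description of single genes. It stays among the 18 glycolytic enzymes in the counts, medians, tests and means of that list. Which other genes of the lists are affected was not examined. Symbols were taken from the deposited tables, and positions from the GENCODE M21 annotation of the same build (GRCm38), counted from 1; 54409 identifiers matched it and 37 did not. A symbol occurred for more than 1 identifier in 94 cases, and 27384 genes had a count of 0 in every library.

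Library totals were 13082947 to 20960505 counts. A level is given in CPM, counts scaled so that a library sums to 1000000. The floor, the level of 3 counts, lay between 0.143 and 0.229 CPM depending on the library. Floors cover counting error only, since PCR duplicates cannot be recognised in gene counts, while the 95% intervals of folds rest on the SE of the fit and those of correlations on the 12 libraries. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical in part; 3 of the groups held both sexes and thus more than 1 animal. The pair of most similar libraries still differed far beyond sampling noise (chi-square per degree of freedom 24.3), so no library was taken as a second sequencing of another. This leaves open whether any of them came from the same animal.

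The samples were grouped by their labels, and the comparisons, tests, gene lists and alternatives were fixed before the data were examined. Counts were fitted in R 4.3.3 with edgeR 4.0.16, by glmQLFit and glmQLFTest (the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), with 1 mean per group over all 12 libraries so that the groups shared an estimate of the spread. Trimmed-mean (TMM) factors scaled the libraries and ran from 0.702 to 1.46; folds are scaled by them and levels are not. The filterByExpr function kept 13773 genes, and a gene was called at an adjusted p under 0.05. Standard errors of log2 folds were derived from the F statistic. The 5 planned contrasts were the genotype effect in LPS, the genotype effect in medium, the LPS effect in each genotype, and the interaction. A comparison of the libraries labelled KO medium with WT LPS, and one of those labelled KO LPS with WT medium, were added after the data were seen.

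Of 30 gene lists written beforehand, 14 are described with their genes, and that choice was made after the list results were seen; of the other 16, those that passed camera in a planned contrast are given by their test. The 14 were glycolytic enzymes, glucose and lactate transport and glycolysis regulators, HIF-1 target genes, the tricarboxylic acid cycle, LPS-induced cytokines, chemokines and effectors, interferon-stimulated genes, alternative activation, the NLR, inflammasome and STING pathway, the ATF4 and amino acid response, cholesterol synthesis, the cell cycle, and markers of neutrophils, B cells and stromal cells. Each list was tested with camera (limma 3.58.1, on voom values, preset correlation 0.01), adjusted by Benjamini-Hochberg over the 30 lists of a contrast, then with the correlation estimated from the data and with fry. The named genes followed a fixed rule. Nlrc3 came first. For each contrast the rule took the 6 largest rises and 6 largest falls among called genes with at least 5 CPM in the higher group and no overlap between the groups' libraries (chance gives 10% of genes without overlap for 3 against 3), leaving out unnamed gene models and pseudogenes. It also took the 2 rising and 2 falling members of each list with the smallest p, and a fixed set of glycolytic and inflammatory genes in every contrast. Genes whose groups lay near 0 are given as levels, without a fold.

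Alternatives were DESeq2 1.42.0, limma-voom, relative log expression factors, library size without TMM factors, no low-count filter, a filter of 5 CPM in 3 libraries, fits of the compared groups alone, the replicate number as a block, the code number of 4 WT libraries as a block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), and leaving out each library in turn. Chosen after seeing the data were a sex term, fits of libraries with Y-linked transcripts only, and fits without the libraries labelled KO LPS 2 and 3, doubted for their neutrophil and B cell transcripts, which leave that group 1 library. Fits with a component of the data as a covariate, on a subset of libraries chosen by that component, and without 2 libraries picked for their glycolytic level were run and taken out, because they chose or adjusted libraries by the outcome under test. No value from those fits is given. The procedure was tested on simulated data with 200 changed genes among the real ones. Over the 7 comparisons, edgeR recovered between 75.8% and 93.9% of genes changed 16-fold and 8.96% to 53.7% of those changed 4-fold. It recovered at most 2.99% of those changed 2-fold, with 1 to 7 false calls, so 2-fold changes were mostly out of reach in that setting. The planned contrasts called at least 2526 genes, and the Benjamini-Hochberg threshold is looser the more genes change. Recovery there may thus be higher, and was not simulated. DESeq2, tested this way for the genotype effect in LPS only, made 31 false calls. The recovery required of the procedure at 4-fold was first set by a guess, was not met, and was replaced by checks of fold, direction and the 16-fold tier.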

Results

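Gene expression was measured by RNA sequencing in mouse bone marrow-derived macrophages, cells grown from marrow. The mice carried loxP-flanked Nlrc3 alleles. In the knockout (KO), Cre recombinase under the LysM promoter deletes Nlrc3 in myeloid cells, and the wild type (WT) had no Cre. Cells stayed in medium or received lipopolysaccharide (LPS), a bacterial ligand of a Toll-like receptor, for 12 h. Each of the 4 labelled groups had 3 libraries. Library totals ran from 13082947 to 20960505 counts, with a mean of 16795884.5 ± 2373271 (SD, n = 12). The group means were 16337820 ± 3216863 in WT medium, 17491807 ± 3081641 in WT LPS, 15675813 ± 2109180 in the libraries labelled KO medium and 17678099 ± 1610729 in those labelled KO LPS (SD, n = 3 each). Levels are in counts per 1000000 (CPM), scaled so that each library sums to that number. Between 17243 and 19249 genes had a count in a library. Xist, a transcript of the inactive X chromosome, lay between 95.1 and 634 CPM in 5 libraries, namely WT medium 1 and 3, WT LPS 2 and the libraries labelled KO LPS 2 and 3. The other 7 libraries carried Y-linked transcripts, among them all 3 labelled KO medium, so sex was mixed unevenly over the groups.

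Nlrc3, a member of the NOD-like receptor family and the targeted gene, was examined first as a check of the labels. It lies on chromosome 16 at 3945007 to 3976632 of mm10, on the minus strand (ENSMUSG00000049871). Nlrc3 stood at 9.89, 13.6 and 10.4 CPM in WT medium libraries 1 to 3 and at 0.796, 4.39 and 1.40 CPM in WT LPS. In the libraries labelled KO medium it stood at 0.996, 0.850 and 0.876 CPM, and in those labelled KO LPS at 15.6, 8.29 and 6.04 CPM. The group means were 11.3 ± 2.02, 2.19 ± 1.92, 0.907 ± 0.0777 and 9.98 ± 4.99 CPM in that order (SD, n = 3 each). Under LPS, Nlrc3 was thus higher in the libraries labelled KO than in WT, by 1.76 ± 0.52 (log2 fold ± SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0298). That call ended without WT LPS 1 (adjusted p = 0.103, same edgeR test and Benjamini-Hochberg adjustment), WT LPS 3 (0.137), KO LPS 1 (0.0873) or KO LPS 2 (0.0569). In medium, Nlrc3 was lower in the libraries labelled KO, with a log2 fold of −2.83 ± 0.56 (edgeR, Benjamini-Hochberg adjusted p = 0.0037). With LPS, Nlrc3 fell in WT by 1.89 ± 0.53 (edgeR, Benjamini-Hochberg adjusted p = 0.0268), a call that ended without WT LPS 1 (0.0896), WT LPS 3 (0.128), WT medium 1 (0.0511) or WT medium 2 (0.0719). The libraries labelled KO medium 1 to 3 also had the LPS-responsive gene Nos2 at 2717, 1148 and 2347 CPM, against at most 8.35 CPM in WT medium. Set against WT LPS, their Nlrc3 was at 52.1% (95% interval 24.7% to 110%). Their lower Nlrc3 than in WT medium is thus no separate sign of a knockout. It cannot be told apart from a fall like that of WT with LPS. Between 114 and 247 reads stood behind each library labelled KO LPS. Because Nlrc3 went against the label of the KO LPS libraries, every direction below that involves the KO is that of libraries labelled so. Whether the counted reads fell on deleted exons cannot be read from gene counts.

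**Figure D1:**
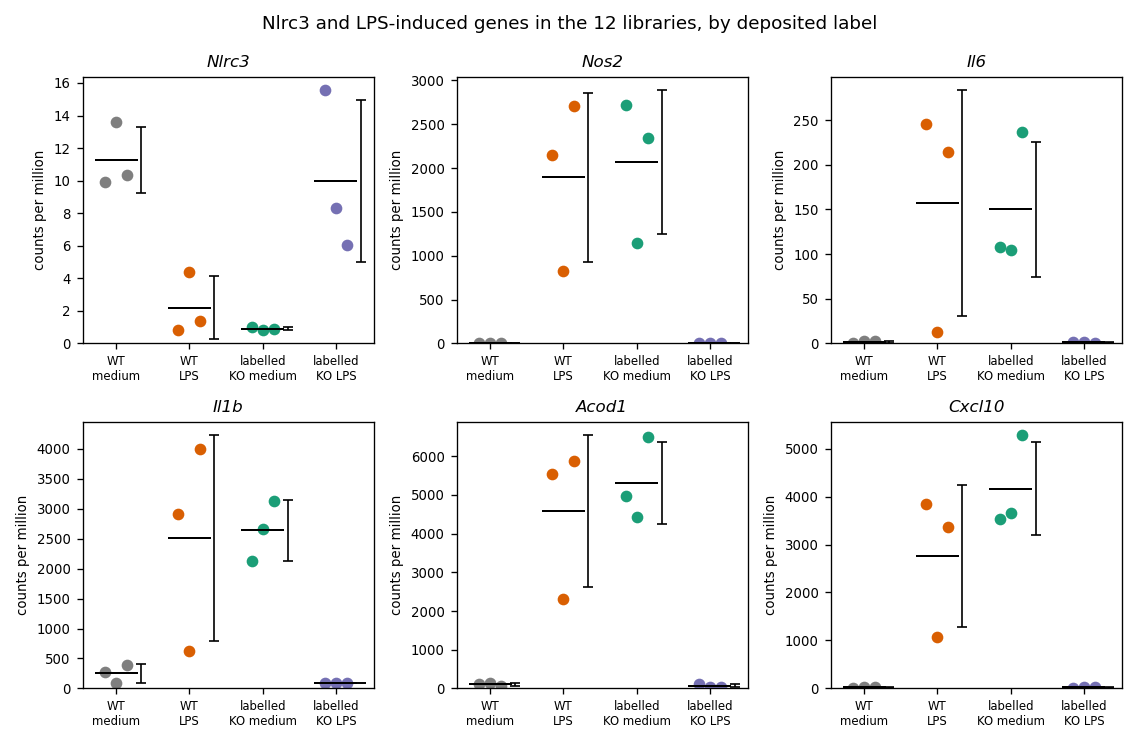
Levels in CPM of Nlrc3, Nos2, Il6, Il1b, Acod1 and Cxcl10 by labelled group; points are libraries, lines means and bars SD (n = 3 per group). Nos2 lay between 831 and 2717 CPM in WT LPS and in the libraries labelled KO medium, and at most at 8.35 CPM in WT medium and in those labelled KO LPS.

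The comparison of WT cells with and without LPS asked what LPS did where Nlrc3 was intact. Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), went from 6.06 ± 2.23 CPM in medium to 1896 ± 963 CPM in LPS (SD, n = 3 each). The cytokine Il6 (chromosome 5, 30013114 to 30019981) went from 1.70 ± 1.21 to 157 ± 127 CPM and Il1b (chromosome 2, 129364570 to 129371139) from 250.4 ± 156 to 2516 ± 1722 CPM. Acod1, which makes itaconate (chromosome 14, 103046977 to 103056573), went from 104 ± 45.1 to 4582 ± 1972 CPM. The WT LPS libraries were uneven, and WT LPS 2 was lowest in each of these genes. In WT LPS 1 to 3, Il6 stood at 245, 12.3 and 214 CPM, Il1b at 2915, 630 and 4005 CPM and Tnf at 754, 114 and 528 CPM, so that library widens the SD of WT LPS here and below. On the log2 scale Nos2 rose by 8.98 ± 0.93 (SE), Il6 by 7.23 ± 1.15, Il1b by 4.09 ± 0.68, Acod1 by 6.07 ± 0.68, the chemokine Ccl5 by 8.44 ± 0.57, Tnf (chromosome 17, 35199381 to 35202007) by 3.98 ± 0.89, the anti-inflammatory Il10 by 5.47 ± 0.57 and Ifnb1, a type I interferon, by 3.87 ± 0.86. Adjusted p of these genes lay between 1.5e-05 for Ccl5 and 0.0090 for Tnf (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Cxcl11, Il23r and Shisa3 were near the floor in medium, at 0.273, 0.0203 and 0.0255 CPM, and stood at 155 ± 57.3, 10.2 ± 3.87 and 8.20 ± 6.36 CPM in LPS. The largest falls that held with any library left out were Mcoln3, a lysosomal channel (−5.87 ± 1.16), St6gal1, a sialyltransferase (−4.88 ± 0.78), Zfyve28 (−4.33 ± 0.74), Amz1 (−4.30 ± 0.50) and Lpin1, a phosphatidate phosphatase (−4.30 ± 0.89).

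By list, all 40 measured interferon-stimulated genes rose with LPS in WT, over all genes and adjusted over the list alone. For the list, camera gave a Benjamini-Hochberg adjusted p = 2.3e-41, and adjusted p = 0.0451 with an estimated correlation. Among them Ifit2, Isg20 and Gbp3 rose by 4.79 ± 0.38, 5.73 ± 0.42 and 5.29 ± 0.45. Of 32 LPS-induced cytokines, chemokines and effectors, 29 rose over all genes and 29 adjusted over the list alone. Camera gave the list a Benjamini-Hochberg adjusted p = 4.8e-20, and adjusted p = 0.213 with an estimated correlation. Of 22 genes of the NLR, inflammasome and STING pathway, 13 rose, among them Il18 (3.35 ± 0.36) and Casp4 (3.40 ± 0.46), a sensor of intracellular LPS, and 13 rose and 1 fell adjusted over the list alone. The list passed camera with a Benjamini-Hochberg adjusted p = 1.4e-05, against adjusted p = 0.213 with an estimated correlation. Cholesterol synthesis had 4 lower members of 21, over all genes and adjusted over the list alone, with Dhcr7 at −2.57 ± 0.40 and a median of −1.07. Tested by camera, the list had a Benjamini-Hochberg adjusted p = 8.0e-04, and adjusted p = 0.868 with an estimated correlation. Of 20 genes of the ATF4 and amino acid response, 5 rose and 2 fell, and 8 rose and 3 fell adjusted over the list alone, with Nupr1 at 4.13 ± 0.46 and Atf5 at −1.29 ± 0.27. In the camera test, the list had a Benjamini-Hochberg adjusted p = 0.0270, and adjusted p = 0.304 with an estimated correlation. Alternative activation had 4 higher members of 18 and 1 lower, likewise adjusted over the list alone, among them the interleukin 4 receptor Il4ra (3.41 ± 0.34), and did not pass as a list (camera, Benjamini-Hochberg adjusted p = 0.223). The cell cycle list had 1 lower gene of 32 and 0 adjusted over the list alone, with a median of −0.47. The list's camera test gave a Benjamini-Hochberg adjusted p = 0.0270, and adjusted p = 0.878 with an estimated correlation. When libraries were scaled by size only, cholesterol synthesis had 12 lower members, the cell cycle 7 and alternative activation 3 higher and 2 lower.

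Among 18 glycolytic enzymes, 5 rose with LPS in WT, the hexokinases Hk1 (1.39 ± 0.29), Hk2 (1.82 ± 0.31) and Hk3 (1.81 ± 0.30) and the phosphofructokinases Pfkl (1.61 ± 0.27) and Pfkp (1.71 ± 0.45). Adjusted over the list alone, 7 rose and 2 fell. Scaled by library size only, 4 were higher and 4 lower, and the median moved from 0.83 to 0.30. For the list, camera gave a Benjamini-Hochberg adjusted p = 0.0270, and adjusted p = 0.771 with an estimated correlation. The last steps did not pass: Pkm (chromosome 9, 59656368 to 59679375) was at 0.65 ± 0.39 and Ldha (chromosome 7, 46841475 to 46855627) at 0.99 ± 0.57, with adjusted p = 0.288 and 0.258 (edgeR, Benjamini-Hochberg); without WT medium 2, Ldha passed at 0.0309. Of 17 genes of glucose and lactate transport and glycolysis regulators, 7 rose and 1 fell (7 and 2 adjusted over the list alone), and the list did not pass (camera, Benjamini-Hochberg adjusted p = 0.223); its median of 0.15 became −0.42 when libraries were scaled by size only. Within it Pfkfb3, which makes the activator of phosphofructokinase (chromosome 2, 11471433 to 11554077), rose from 96.4 ± 59.3 to 977 ± 213 CPM (log2 4.02 ± 0.55). The glucose transporter Slc2a1 (chromosome 4, 119108711 to 119137983) rose by 2.08 ± 0.52 (edgeR, Benjamini-Hochberg adjusted p = 0.0155), a call that ended without WT LPS 3 (0.0843), WT medium 1 (0.0680) or WT medium 3 (0.0610). HIF-1 target genes had 7 higher and 1 lower of 24, 8 and 1 adjusted over the list alone, with Ak4 at 3.24 ± 0.37 and Bnip3 at 2.57 ± 0.41. Camera gave the list a Benjamini-Hochberg adjusted p = 0.0021, and adjusted p = 0.457 with an estimated correlation. By library size only, 5 were higher and 2 lower. Hif1a itself (chromosome 12, 73901375 to 73947530) rose by 1.90 ± 0.50 (edgeR, Benjamini-Hochberg adjusted p = 0.0209), not without WT LPS 3 (0.0973) or WT medium 1 (0.0653). In the tricarboxylic acid cycle, 5 of 20 genes fell, over all genes and adjusted over the list alone, among them the isocitrate dehydrogenases Idh1 (−2.58 ± 0.37) and Idh2 (−1.24 ± 0.25). The list passed camera with a Benjamini-Hochberg adjusted p = 0.0335, against adjusted p = 0.868 with an estimated correlation. By library size only, 9 were lower. Ribosomal proteins (0 of 55 called, median −0.50) passed camera as lower, with a Benjamini-Hochberg adjusted p = 0.0271 and adjusted p = 0.966 with an estimated correlation.

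Markers of other cell types were counted in the same comparison. Neutrophil and granule markers had 2 higher of 14 (2 higher and 1 lower adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.402), and B cell markers 0 of 8 by edgeR, and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.750). Stromal and fibroblast markers had 1 higher of 15, the receptor Pdgfrb (2.22 ± 0.44), also adjusted over the list alone, with a median of 1.54. Tested by camera, the list had a Benjamini-Hochberg adjusted p = 0.0270, and adjusted p = 0.878 with an estimated correlation. Over all 13773 genes, 1636 rose and 890 fell (2526; 64.8% higher). Scaling by library size only made 24.4% higher and moved the median of all genes from −0.06 to −0.64. Without WT LPS 3, WT medium 1 or WT medium 3 the total was 1384, 1493 or 1545, and without WT LPS 2 it was 3042.

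Under LPS, the libraries labelled KO were set against WT, the question in the study's title. The inflammatory genes stood far lower in the libraries labelled KO LPS, whose label goes against Nlrc3: Nos2 at 2.51 ± 2.55 CPM against 1896 ± 963 in WT LPS, Il6 at 1.02 ± 0.313 against 157 ± 127, Il1b at 87.1 ± 3.67 against 2516 ± 1722 and Acod1 at 64.8 ± 36.5 against 4582 ± 1972 CPM (SD, n = 3 each). The log2 folds were −10.13 ± 0.98 for Nos2, −7.88 ± 1.19 for Il6, −5.45 ± 0.73 for Il1b, −6.71 ± 0.70 for Acod1, −7.61 ± 0.55 for Ccl5, −5.34 ± 0.57 for Il10, −4.42 ± 0.88 for Ifnb1 and −3.83 ± 0.88 for Tnf (SE). Adjusted p of these lay between 2.2e-05 for Ccl5 and 0.0091 for Tnf (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Cxcl11, Il1f6, Il23r and Il19 stood at 0.208, 0.0177, 0.0177 and 0.372 CPM in the libraries labelled KO LPS and at 155, 15.6, 10.2 and 117 CPM in WT LPS. Higher in the libraries labelled KO LPS were Retnlg, a granulocyte transcript (36.2 ± 27.4 against 0.191 ± 0.237 CPM), Lpin1 (43.0 ± 30.4 against 0.844 ± 0.872 CPM), St6gal1 (74.8 ± 53.1 against 1.495 ± 0.565 CPM) and Mcoln3 (17.7 ± 12.5 against 0.450 ± 0.321 CPM). For Retnlg the libraries labelled KO LPS 1 to 3 stood at 4.54, 52.2 and 51.7 CPM.

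**Figure D2:**
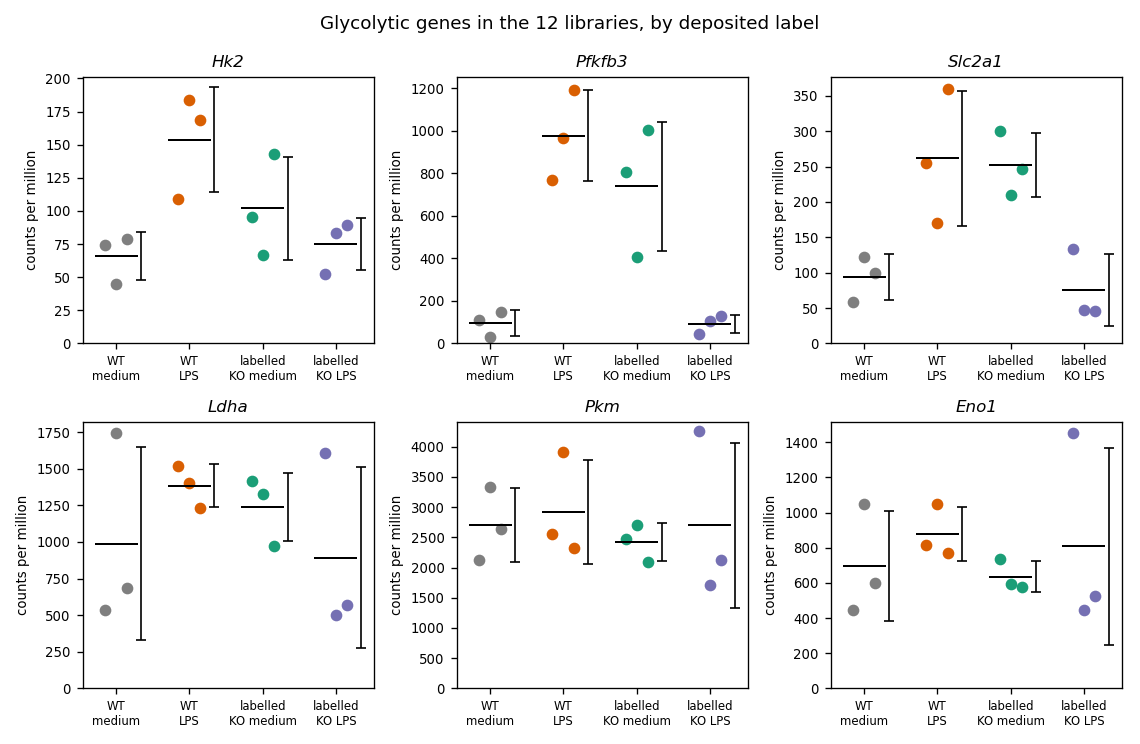
Levels in CPM of Hk2, Pfkfb3, Slc2a1, Ldha, Pkm and Eno1 by labelled group; points are libraries, lines means and bars SD (n = 3 per group). Pfkfb3 averaged 977 CPM in WT LPS and 738 CPM in the libraries labelled KO medium, against 96.4 CPM in WT medium and 92.6 CPM in those labelled KO LPS, while Pkm lay between means of 2423 and 2926 CPM.

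Of 18 glycolytic enzymes, 5 were lower in the libraries labelled KO LPS and 2 higher (7 and 2 adjusted over the list alone), and the list as a whole did not pass (median −0.71; camera, Benjamini-Hochberg adjusted p = 0.0846, adjusted p = 0.816 with an estimated correlation). It passed at 0.0198 without the library labelled KO LPS 1. Scaled by library size only, 4 were lower and 5 higher, with a median of −0.20, so the number of lower and higher enzymes depends on the scaling. Lower were Hk2 (chromosome 6, 82725025 to 82774454) at 75.1 ± 19.8 against 154 ± 39.7 CPM (log2 −1.53 ± 0.30), Hk3 (−1.55 ± 0.30), Pfkl (−1.69 ± 0.27), Pfkp (−1.69 ± 0.45) and Pgk1, phosphoglycerate kinase (−1.32 ± 0.44). Higher were the enolases Eno2 (1.09 ± 0.28; edgeR, Benjamini-Hochberg adjusted p = 0.0151) and Eno3 (1.13 ± 0.31; 0.0213). The Eno2 call ended without WT LPS 1 (0.0504), WT LPS 3 (0.0538) or KO LPS 2 (0.0593), and the Eno3 call without the same libraries (0.0746, 0.0633 and 0.0769). Pkm (−0.59 ± 0.39) and Ldha (−1.15 ± 0.57) did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.293 and 0.164), but both did without the library labelled KO LPS 1 (0.0432 and 0.0300). Glucose and lactate transport and glycolysis regulators had 7 lower and 3 higher of 17 (7 and 4 adjusted over the list alone); the median was 4.1e-06, 0.50 when scaled by library size only, while the mean and camera pointed down (mean −0.54; Benjamini-Hochberg adjusted p = 0.428). Among them Pfkfb3 (−3.92 ± 0.55), Slc2a1 (−2.34 ± 0.52) and the transporter Slc2a6 (−3.93 ± 0.63) were lower, and Pdk2, a kinase that inhibits pyruvate dehydrogenase, was higher (2.9998 ± 0.58).

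HIF-1 target genes had 9 lower members of 24 and 0 higher in the libraries labelled KO LPS by edgeR, also adjusted over the list alone, with Ak4 at −3.73 ± 0.38 and Bnip3 at −3.00 ± 0.42. In the camera test, the list had a Benjamini-Hochberg adjusted p = 2.6e-04, and adjusted p = 0.355 with an estimated correlation. Hif1a was lower too, at 74.3 ± 8.37 against 380 ± 115 CPM (log2 −2.88 ± 0.52; edgeR, Benjamini-Hochberg adjusted p = 0.0025). The tricarboxylic acid cycle had 5 higher of 20, also adjusted over the list alone, among them Idh1 (2.19 ± 0.36) and Idh2 (2.06 ± 0.25). The list's camera test gave a Benjamini-Hochberg adjusted p = 0.0062, and adjusted p = 0.816 with an estimated correlation. Cholesterol synthesis had 5 higher of 21, also adjusted over the list alone, with Dhcr7 at 2.95 ± 0.40 and Lss at 2.03 ± 0.34. For the list, camera gave a Benjamini-Hochberg adjusted p = 6.4e-05, and adjusted p = 0.816 with an estimated correlation. Of 40 interferon-stimulated genes, 39 were lower, and all 40 adjusted over the list alone, with Ifit2 at −5.21 ± 0.38. Camera gave the list a Benjamini-Hochberg adjusted p = 2.5e-36, and adjusted p = 0.0670 with an estimated correlation. Of 32 LPS-induced genes, 27 were lower, and 29 adjusted over the list alone. The list passed camera with a Benjamini-Hochberg adjusted p = 1.3e-18, against adjusted p = 0.240 with an estimated correlation. The NLR, inflammasome and STING pathway had 13 lower of 22, 14 adjusted over the list alone, with Casp4 at −4.15 ± 0.48 and Il18 at −3.51 ± 0.36. Tested by camera, the list had a Benjamini-Hochberg adjusted p = 9.1e-06, and adjusted p = 0.240 with an estimated correlation. Alternative activation (4 higher and 3 lower of 18, 4 and 4 adjusted over the list alone) and the ATF4 response (3 higher and 5 lower of 20, 3 and 6 adjusted over the list alone; median 0.22 but mean −0.27) did not pass, each with a camera Benjamini-Hochberg adjusted p = 0.671. With size as the only scaling, HIF-1 target genes had 6 lower and 1 higher, the tricarboxylic acid cycle 15 higher and cholesterol synthesis 15 higher. Alternative activation then had 5 higher and 2 lower, and the ATF4 response and the regulators and transporters as many higher as lower (4 and 6 each way). Ribosomal proteins (0 of 55 called, median 0.49) passed camera as higher, with a Benjamini-Hochberg adjusted p = 0.0062 and adjusted p = 0.853 with an estimated correlation.

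The cell cycle list had 6 higher and 1 lower of 32 in the libraries labelled KO LPS, also adjusted over the list alone, with the replication licensing factors Mcm2 at 1.88 ± 0.41 and Mcm7 at 1.88 ± 0.39. In the camera test, the list had a Benjamini-Hochberg adjusted p = 0.0062, and adjusted p = 0.816 with an estimated correlation. By library size only, 18 were higher and 0 lower. Beside them, 5 of 14 neutrophil and granule markers were higher, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.130). The mean log2 CPM of the 14 markers, scaled by the TMM factors, was 7.10 and 7.67 in the libraries labelled KO LPS 2 and 3. It was also raised in WT LPS 3 (5.93) and labelled KO medium 3 (6.07), against at most 4.89 in the other libraries. The marker S100a8 was highest in WT LPS 3, at 1324 CPM. Mpo, myeloperoxidase, stood at 13.001, 308 and 716 CPM in the libraries labelled KO LPS 1 to 3 and between 3.72 and 46.3 CPM in the other groups. B cell markers had 3 higher of 8, and 4 adjusted over the list alone, with the receptor component Cd79b at 2.97 ± 0.66 and at 5.68, 42.2 and 44.6 CPM in those 3 libraries. The list's camera test gave a Benjamini-Hochberg adjusted p = 0.0304, and adjusted p = 0.816 with an estimated correlation. Stromal and fibroblast markers had 4 lower of 15, and 6 adjusted over the list alone, among them Pdgfrb (−2.04 ± 0.44). For the list, camera gave a Benjamini-Hochberg adjusted p = 0.0062, and adjusted p = 0.816 with an estimated correlation. Over all genes 1435 were higher and 1889 lower (3324; 43.2% higher), and with scaling by library size only 74.5% were higher and the median of all genes moved from 0.06 to 0.57. The total was 3489 without WT LPS 2, 1822 without WT LPS 3, 1810 without KO LPS 2, 1982 without KO LPS 3 and 536 without both of these KO LPS libraries, which leaves that group 1 library. How much of that drop comes from the lost replicates was not tested.

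In medium, the libraries labelled KO were set against WT to ask what loss of Nlrc3 did without LPS. The inflammatory genes were higher in the libraries labelled KO medium: Nos2 at 2071 ± 820.3 against 6.06 ± 2.23 CPM, Il6 at 150.02 ± 75.3 against 1.70 ± 1.21, Il1b at 2641 ± 507 against 250.4 ± 156 and Acod1 at 5309 ± 1069 against 104 ± 45.1 CPM (SD, n = 3 each). The log2 folds were 9.27 ± 0.95, 7.25 ± 1.15, 4.30 ± 0.69 and 6.44 ± 0.69 for these genes, 8.77 ± 0.58 for Ccl5, 5.86 ± 0.58 for Il10, 4.83 ± 0.92 for Tnf and 3.93 ± 0.86 for Ifnb1. Adjusted p lay between 1.3e-05 for Ccl5 and 0.0065 for Ifnb1 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Lhx2, a LIM homeobox factor, stood at 43.4 ± 12.8 against 0.206 ± 0.0233 CPM. Among the largest falls, Tmem273 stood at 0.338 ± 0.199 against 32.2 ± 4.24 CPM and Stard9, a kinesin, at 1.06 ± 0.485 against 104 ± 71.8 CPM.

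All 40 interferon-stimulated genes were higher in the libraries labelled KO medium, over all genes and adjusted over the list alone, among them Isg20 at 5.99 ± 0.42 and Ifit2 at 5.06 ± 0.38. Camera gave the list a Benjamini-Hochberg adjusted p = 1.2e-35, and adjusted p = 0.0699 with an estimated correlation. Of 32 LPS-induced genes, 27 were higher, and 29 adjusted over the list alone. The list passed camera with a Benjamini-Hochberg adjusted p = 1.5e-18, against adjusted p = 0.329 with an estimated correlation. The NLR, inflammasome and STING pathway had 12 higher and 1 lower of 22, also adjusted over the list alone, with Casp4 at 3.77 ± 0.47. Tested by camera, the list had a Benjamini-Hochberg adjusted p = 3.4e-04, and adjusted p = 0.412 with an estimated correlation. Of 18 glycolytic enzymes 5 were higher and 1 lower, also adjusted over the list alone, and the list did not pass (camera, Benjamini-Hochberg adjusted p = 0.0805); its median of 0.76 became −0.02 when libraries were scaled by size only, with 2 higher and 5 lower. Hk2 (1.46 ± 0.30), Hk3 (2.04 ± 0.30), Hk1 (1.41 ± 0.29), Pfkl (1.43 ± 0.27) and Pfkp (2.16 ± 0.46) were the higher members. The median of glucose and lactate transport and glycolysis regulators was −0.08 and their mean 0.64, with 7 higher and 4 lower of 17, also adjusted over the list alone (camera pointing up, Benjamini-Hochberg adjusted p = 0.381). Among them Pfkfb3 was at 3.82 ± 0.55, Slc2a1 at 2.22 ± 0.52, Slc2a6 at 4.63 ± 0.65 and Pdk2 at −2.73 ± 0.59. Pkm (0.64 ± 0.39) and Ldha (1.07 ± 0.57) did not pass, with edgeR Benjamini-Hochberg adjusted p = 0.248 and 0.189; without WT medium 2, Ldha passed at 0.0185.

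HIF-1 target genes had 7 higher and 1 lower of 24 in the libraries labelled KO medium, also adjusted over the list alone, with Ak4 at 3.05 ± 0.36 and the prolyl hydroxylase subunit P4ha1 at 1.68 ± 0.31 (camera, Benjamini-Hochberg adjusted p = 0.0960); the median was 0.62, and −0.23 when scaled by library size only. Hif1a was higher by 1.70 ± 0.50 (edgeR, Benjamini-Hochberg adjusted p = 0.0265), not without WT medium 1 (0.0747), KO medium 1 (0.0613) or KO medium 3 (0.106). Lists that did not pass included the tricarboxylic acid cycle, with 2 lower of 20, cholesterol synthesis, with 4 lower of 21, and alternative activation, with 4 higher of 18 (2, 4 and 3 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.40006, 0.199 and 0.199). The nuclear-encoded respiratory chain, with 1 higher of 60 and 0 adjusted over the list alone, passed as higher (median 0.66; camera, Benjamini-Hochberg adjusted p = 0.0032, and adjusted p = 0.909 with an estimated correlation), but its median was −0.09 when scaled by library size only. Idh1 (−2.77 ± 0.37) and Dhcr7 (−2.65 ± 0.40) were among the lower genes and Il4ra (3.67 ± 0.34) among the higher. The ATF4 response had 5 higher and 3 lower of 20 (6 and 3 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.346), and its median of 0.41 became −0.38 when scaled by library size only. The cell cycle list had 1 higher and 5 lower of 32 (1 and 3 adjusted over the list alone), with Mcm2 at −1.87 ± 0.42 (camera, Benjamini-Hochberg adjusted p = 0.0805). Neutrophil markers had 2 higher of 14, B cell markers 0 of 8 and stromal markers 1 of 15 by edgeR, the same numbers adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.460, 0.853 and 0.381). Over all genes 1932 were higher and 1688 lower (3620; 53.4% higher), and with scaling by library size only 16.1% were higher and the median of all genes moved from −0.02 to −0.85. Under that scaling the tricarboxylic acid cycle had 12 lower members, cholesterol synthesis 13 and the cell cycle 14, HIF-1 target genes had 4 higher and 5 lower, and alternative activation 4 higher and 3 lower. The ATF4 response had 3 higher and 6 lower, the regulators and transporters 5 and 7 and neutrophil markers 1 and 2. The total was 2196 without WT medium 1, 2235 without WT medium 3 and 2269 without KO medium 1.

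The libraries labelled KO LPS were then set against those labelled KO medium, to ask what LPS did without Nlrc3. By these labels, LPS genes were lower with LPS, with log2 folds of −10.42 ± 0.99 for Nos2, −7.90 ± 1.19 for Il6, −5.66 ± 0.73 for Il1b, −7.08 ± 0.71 for Acod1, −7.94 ± 0.56 for Ccl5, −5.72 ± 0.58 for Il10, −4.67 ± 0.92 for Tnf and −4.48 ± 0.89 for Ifnb1 (SE). Adjusted p lay between 1.4e-05 for Ccl5 and 0.0033 for Ifnb1 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), while Nlrc3 itself was higher by 2.71 ± 0.56 (0.0041). Tnf stood at 759 ± 132 CPM in the libraries labelled KO medium and 49.6 ± 47.1 CPM in those labelled KO LPS (SD, n = 3 each). Higher in the libraries labelled KO LPS were Lpin1 (6.05 ± 0.99) and Retnlg (5.80 ± 1.08). Retnlg stood at 4.54, 52.2 and 51.7 CPM in the libraries labelled KO LPS 1 to 3, so mainly KO LPS 2 and 3 carried it.

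Of 40 interferon-stimulated genes 39 were lower in the libraries labelled KO LPS, also adjusted over the list alone, with Gbp3 at −6.06 ± 0.46 and Ifit2 at −5.47 ± 0.39. In the camera test, the list had a Benjamini-Hochberg adjusted p = 2.5e-33, and adjusted p = 0.0875 with an estimated correlation. LPS-induced genes had 28 lower of 32, also adjusted over the list alone. The list's camera test gave a Benjamini-Hochberg adjusted p = 3.4e-18, and adjusted p = 0.287 with an estimated correlation. The NLR, inflammasome and STING pathway had 14 lower and 2 higher of 22, also adjusted over the list alone. For the list, camera gave a Benjamini-Hochberg adjusted p = 1.1e-04, and adjusted p = 0.287 with an estimated correlation. Glycolytic enzymes had 5 lower and 1 higher of 18 (5 and 2 adjusted over the list alone) and did not pass (camera, Benjamini-Hochberg adjusted p = 0.135); the median of −0.73 became 0.005 when scaled by library size only, with 3 lower and 4 higher. Hk2 was at −1.17 ± 0.30, Hk3 at −1.77 ± 0.30, Pfkl at −1.52 ± 0.27 and Pfkp at −2.13 ± 0.46. Pkm (−0.59 ± 0.39) and Ldha (−1.22 ± 0.57) did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.273 and 0.125), but both did without KO LPS 1 (0.0372 and 0.0221). Of the regulators and transporters 7 were lower and 5 higher of 17, also adjusted over the list alone, with a median of 0.11, a mean of −0.47 and camera pointing down (Benjamini-Hochberg adjusted p = 0.476). Pfkfb3 was at −3.73 ± 0.54, Slc2a1 at −2.48 ± 0.52, Slc2a6 at −4.64 ± 0.65, Pdk2 at 3.43 ± 0.61 and Pfkfb4 at 1.53 ± 0.34. HIF-1 target genes had 7 lower and 1 higher of 24 (9 and 1 adjusted over the list alone), with Ak4 at −3.54 ± 0.37 (camera, Benjamini-Hochberg adjusted p = 0.0193, and adjusted p = 0.872 with an estimated correlation), and Hif1a was at −2.67 ± 0.52. Scaled by library size only, that list had 4 lower and 3 higher, and its median moved from −0.83 to −0.11.

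The cell cycle list had 12 higher and 2 lower of 32 in the libraries labelled KO LPS, and 13 and 2 adjusted over the list alone, with Mcm2 at 2.66 ± 0.43 and Mcm3 at 1.83 ± 0.32. Camera gave the list a Benjamini-Hochberg adjusted p = 0.0184, and adjusted p = 0.896 with an estimated correlation. Beside it, 5 of 14 neutrophil markers and 3 of 8 B cell markers were higher, 5 and 6 adjusted over the list alone, with Cd79b at 3.52 ± 0.69 (camera, Benjamini-Hochberg adjusted p = 0.140 and 0.0468, the latter with adjusted p = 0.896 with an estimated correlation). Cholesterol synthesis had 5 higher of 21, also adjusted over the list alone, with Dhcr7 at 3.03 ± 0.41 and the sterol carrier Stard4 at 2.05 ± 0.36. The list passed camera with a Benjamini-Hochberg adjusted p = 0.0382, against adjusted p = 0.896 with an estimated correlation. The tricarboxylic acid cycle had 5 higher and 1 lower of 20, also adjusted over the list alone, and did not pass (camera, Benjamini-Hochberg adjusted p = 0.128), with Idh1 at 2.37 ± 0.36 and Idh2 at 1.82 ± 0.25. Nor did alternative activation (3 higher and 3 lower of 18, 3 and 5 adjusted over the list alone), the ATF4 response (5 and 5 of 20, likewise adjusted over the list alone) or stromal markers (1 lower of 15, likewise), with camera Benjamini-Hochberg adjusted p = 0.560, 0.847 and 0.128. The nuclear-encoded respiratory chain, with 1 lower of 60, also adjusted over the list alone, passed as lower (median −0.86; camera, Benjamini-Hochberg adjusted p = 0.0184, and adjusted p = 0.896 with an estimated correlation), but had a median of −0.09 and 8 higher when scaled by library size only. Over all genes 2082 were higher and 2104 lower (4186; 49.7% higher), and with scaling by library size only 81.9% were higher and the median of all genes moved from 0.04 to 0.78. Under that scaling the cell cycle had 21 higher members, the tricarboxylic acid cycle 14 and cholesterol synthesis 12, each with 0 lower, and alternative activation had 6 higher and 2 lower. The ATF4 response had 9 higher and 4 lower, its median moving from 0.47 to 1.19, the regulators and transporters 7 and 6, neutrophil markers 7 and 0 and B cell markers 6 and 0. The total was 2543 without KO LPS 2, 2630 without KO LPS 3, 2713 without KO medium 1 and 862 without KO LPS 2 and 3, again with 1 library left in that group.

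The interaction asked whether the LPS effect differed between the labelled genotypes, as the LPS effect in the libraries labelled KO minus that in WT. The difference was −19.40 ± 1.36 for Nos2, −16.38 ± 0.80 for Ccl5, −15.13 ± 1.65 for Il6, −13.15 ± 0.99 for Acod1, −11.20 ± 0.81 for Il10, −10.27 ± 0.54 for Ifit2, −9.75 ± 1.00 for Il1b, −8.65 ± 1.28 for Tnf and −8.35 ± 1.24 for Ifnb1 (log2 ± SE), with adjusted p between 3.1e-07 for Ccl5 and 2.6e-04 for Ifnb1 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). For Nlrc3 it was 4.59 ± 0.77 (edgeR, Benjamini-Hochberg adjusted p = 5.9e-04). It was positive for Lpin1 (10.35 ± 1.33), St6gal1 (10.09 ± 1.12), Dhcr7 (5.60 ± 0.57) and Idh1 (4.95 ± 0.52). All 40 interferon-stimulated genes had a lower LPS effect in the libraries labelled KO, also adjusted over the list alone, and so had 30 of 32 LPS-induced genes (31 adjusted over the list alone), with camera Benjamini-Hochberg adjusted p = 2.2e-32 and 3.3e-18 and adjusted p = 0.0466 for each with an estimated correlation. The NLR, inflammasome and STING pathway had 13 negative and 2 positive of 22 (14 and 2 adjusted over the list alone). Tested by camera, the list had a Benjamini-Hochberg adjusted p = 6.2e-05, and adjusted p = 0.2996 with an estimated correlation.

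**Figure D3:**
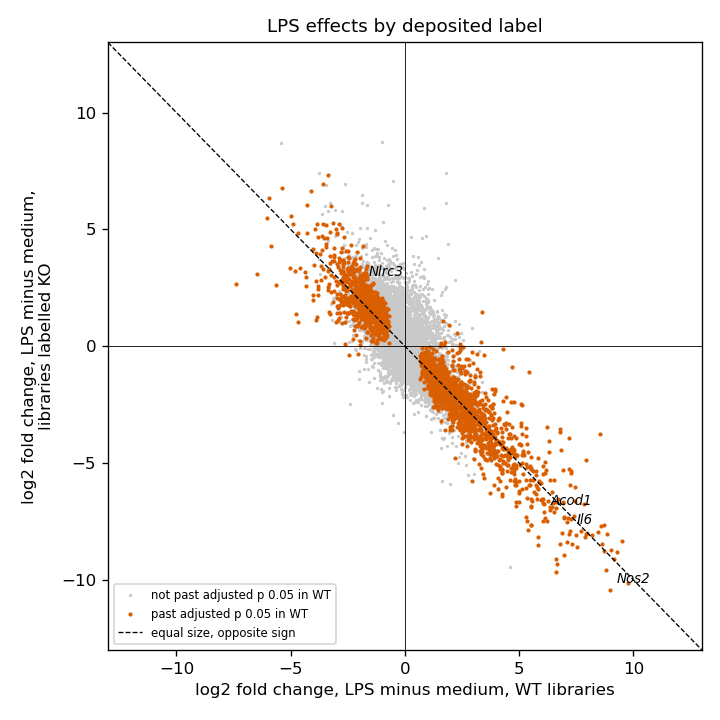
Each point is a gene, with its log2 fold change of LPS against medium in WT on the x axis and in the libraries labelled KO on the y axis; orange marks genes called in WT, and the dashed line is an equal effect of opposite sign. Of the 2526 genes called in WT, 99.5% had the opposite sign in the libraries labelled KO.

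Of 18 glycolytic enzymes 8 had a negative and 2 a positive interaction, also adjusted over the list alone, and the list did not pass (median −1.61; camera, Benjamini-Hochberg adjusted p = 0.0625). The interaction was −2.99 ± 0.43 for Hk2, −3.59 ± 0.42 for Hk3, −3.12 ± 0.38 for Pfkl, −7.74 ± 0.78 for Pfkfb3, −4.56 ± 0.74 for Slc2a1 and −4.58 ± 0.72 for Hif1a. It was −1.24 ± 0.55 for Pkm (edgeR, Benjamini-Hochberg adjusted p = 0.0943), which passed without KO LPS 1 (0.0134) or WT medium 2 (0.0495). Ldha, at −2.22 ± 0.81 (edgeR, Benjamini-Hochberg adjusted p = 0.0449), passed when either of these libraries was left out (0.0083 and 0.0045) but not when any of the other 10 was, with values of 0.102, 0.0517 and 0.0845 without WT LPS 1 to 3, 0.101 and 0.101 without KO LPS 2 and 3, 0.0951 and 0.0983 without WT medium 1 and 3, and 0.107, 0.1004 and 0.0575 without KO medium 1 to 3. Transport and regulators had 7 negative and 4 positive of 17, also adjusted over the list alone, with a median of 0.11 and camera pointing down (Benjamini-Hochberg adjusted p = 0.516). HIF-1 target genes had 12 negative and 1 positive of 24, also adjusted over the list alone. In the camera test, the list had a Benjamini-Hochberg adjusted p = 0.0054, and adjusted p = 0.705 with an estimated correlation. Cholesterol synthesis had 7 positive of 21 and the cell cycle 13 positive and 2 negative of 32, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0054 and 0.0142, each with adjusted p = 0.873 with an estimated correlation). Stromal markers had 5 negative of 15, and 8 adjusted over the list alone, with Pdgfrb at −4.40 ± 0.62. The list's camera test gave a Benjamini-Hochberg adjusted p = 0.0378, and adjusted p = 0.873 with an estimated correlation. The tricarboxylic acid cycle (6 positive and 1 negative of 20), neutrophil markers (3 and 2 of 14) and B cell markers (3 and 0 of 8) did not pass, with the same numbers adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0742, 0.874 and 0.516). Nor did alternative activation (3 positive and 6 negative of 18) and the ATF4 response (4 and 6 of 20), with the same numbers adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.516 for each); their medians of −1.04 and −0.82 became 0.30 and 0.44 when scaled by library size only. Over all genes 2825 were positive and 2832 negative (5657; 49.9% positive), and with scaling by library size only 81.1% were positive and the median of all genes moved from 0.11 to 1.43. Under that scaling the glycolytic enzymes had 4 negative and 5 positive, with a median of −0.34, and HIF-1 target genes 6 and 5. The cell cycle then had 25 positive, cholesterol synthesis 20 and the tricarboxylic acid cycle 17, and stromal markers had 1 negative. Alternative activation had 7 positive and 4 negative, the ATF4 response 7 and 5, transport and regulators 8 and 7 and neutrophil markers 5 and 0. Without KO LPS 2 and 3 the total was 3624.

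The LPS effects in WT and in the libraries labelled KO share no library, so their calls were compared directly. Called in both were 2147 genes, and all of them had opposite signs. Of these, 1420 were higher with LPS in WT and lower in the libraries labelled KO, where independent lists would share 249.9, and 727 went the other way, where independent lists would share 134.5. Among genes called in WT the slope of the labelled KO effect on the WT effect was −1.0016, with r = −0.953 across genes, which are not independent replicates.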

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

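The 5 contrasts were planned, while the comparisons across both label columns, the splits and the tests of explanations in this part were chosen only after the results they bear on had been seen. Both results below were noted because the LPS effect differed between the labelled genotypes, by the test of the difference itself. That difference passed for 5657 genes (edgeR quasi-likelihood interaction test with Benjamini-Hochberg adjustment), and 2147 genes were called in both LPS effects with opposite signs. The real division was 1 of 100 divisions of the 12 libraries into labelled genotypes. It alone gave as many calls, and the highest of the others gave 3887. The other divisions mixed libraries with high and low LPS genes within a group, which widens the spread. The result therefore shows only that the labelled groups line up with the level of LPS genes. It cannot tell an effect of genotype from exchanged labels. For the 4 contrasts of 3 libraries against 3, the 10 possible splits are too few for a share under 0.05. The real split gave 3324 genes for the genotype effect in LPS, 3620 for that in medium and 4186 for the LPS effect in the libraries labelled KO, each against 0 in the highest other split, and 2526 for the LPS effect in WT against 9.

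The first pattern is that LPS-responsive genes were high in the libraries labelled KO medium and low in those labelled KO LPS. A difference in depth is argued against by its size, a log2 ratio of mean totals of 0.17 between labelled KO LPS and KO medium, since Nos2 differed by −10.42 ± 0.99. If the treatment labels of the KO libraries were exchanged, genes called in WT should turn their sign in the KO, and 99.5% did, but this repeats the pattern over more genes and supports no explanation. Nlrc3 was not called lower across the label columns either (below). Simulated 4-fold changes were recovered in only 43.3% and 52.2% of genes there, a rate over random genes. For Nlrc3 itself, the 95% interval left out a 4-fold loss between labelled KO LPS and WT medium (log2 −1.10 to 0.86). It did not between labelled KO medium and WT LPS (−2.02 to 0.13). A 2-fold loss lay within both, and gene counts do not show exons, so the missing calls do not decide on an exchange. An exchange calls for LPS effects of equal size and opposite sign, and for few differences across both label columns. The slope of the labelled KO on the WT effects was −1.0016, and edgeR called 0 genes in either of those comparisons. An effect of losing Nlrc3 that turns the LPS response around calls only for a slope below 0, of no set size. It allows these values without requiring them, so they do not exclude it. That effect also called for lower Nlrc3 in the libraries labelled KO in both treatments, and under LPS it was higher (log2 1.76 ± 0.52; edgeR, Benjamini-Hochberg adjusted p = 0.0298). Since gene counts do not show whether these reads come from deleted exons, this part of the prediction failed without deciding it. No sample was regrouped on this account, and the labels stand as given.

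The second pattern is that Nlrc3 was higher in the libraries labelled KO LPS than in WT LPS. For the missing decrease against WT medium, too few reads are argued against by at least 114 in each library labelled KO LPS or WT medium. The WT LPS libraries 1 to 3 had only 12, 92 and 23 Nlrc3 reads. The low side of the comparison with WT LPS thus rests on few reads. An exchange of treatment labels leaves Nlrc3 of the libraries labelled KO LPS to be set against WT medium, where the log2 fold was −0.12 (95% interval −1.10 to 0.86; edgeR, Benjamini-Hochberg adjusted p = 0.981) and no knockout is seen either, so an exchange alone may not be enough. Counts from exons outside the deleted part alone would leave at most the WT LPS level. Nlrc3 at 340% of it (95% interval 167% to 692%) goes against them, but this is the pattern itself and no separate test. The call also ended without any one of 4 libraries. Counts from such exons could add to an exchange or to a reversed LPS response. Nlrc3 was at 91.8% of WT medium (95% interval 46.5% to 181%). The libraries labelled KO medium were at 52.1% of WT LPS (24.7% to 110%, log2 −0.94, −2.02 to 0.13). These intervals are too wide, and gene counts do not show exons, so the 2 cannot be told apart. Wrong genotype labels were not tested.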

How the results depend on the processing

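Fits with a sex term, on libraries with Y-linked transcripts, on the 4 WT libraries without a block and without the libraries labelled KO LPS 2 and 3 were chosen only after the results were seen. The 298 named results gave 6270 values under the alternatives. Of these, 9 had another direction, and 134 of the 289 called results kept their call in every alternative run, while 48 lost it when 1 library was left out. For the results that moved, the cause was not tested, except where fewer libraries enter by construction. Simulated 2-fold changes were rarely recovered at this depth and number of libraries. Where these 2 are left out, or only libraries with Y-linked transcripts are kept, a group can hold 1 library, which is assumed to vary like the other groups.

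Leaving out each library in turn gave 1810 to 4093 genes for the genotype effect in LPS, 2196 to 4735 for that in medium, 1384 to 3042 for the LPS effect in WT, 2543 to 5095 for that in the libraries labelled KO and 4709 to 6296 for the interaction. The adjusted p of the glycolytic enzymes for the genotype effect in LPS, 0.0846 by camera with Benjamini-Hochberg adjustment, ran from 0.0198 to 0.175. DESeq2 called 4265, 4523, 3435, 5055 and 6577 genes for the 5 contrasts in that order, and limma-voom 3342, 3471, 2513, 3911 and 5595. With library size only, the genotype effect in medium had 6644 calls, the LPS effect in WT 4233 and that in the libraries labelled KO 6494. With log2(FPKM + 1), which also has no TMM factor, the genotype effect in medium had 6271 and the LPS effect in WT 4421. With log2(FPKM + 0.1) these were 6435 and 4398, and the LPS effect in the libraries labelled KO had 6445. With only the compared groups in the fit, the genotype effect in LPS had 2185 and the LPS effect in WT 1590.

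With only the libraries with Y-linked transcripts, the 5 counts were 1480, 1730, 1445, 1778 and 3701. Without KO LPS 2 and 3 the genotype effect in LPS had 536, the LPS effect in the libraries labelled KO 862 and the interaction 3624. The other adjusted p of the glycolytic list lay between 0.0703 (fry) and 0.816 (estimated correlation).

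Values with another direction were those of Mgl2 (−0.11) and Elane (−0.0256) for the genotype effect in LPS, of Elane (−0.46) for the LPS effect in the libraries labelled KO, and of Elane (−0.72) and Ighm (−0.90) for the interaction, all in libraries with Y-linked transcripts. The others were Elane for the LPS effect in the libraries labelled KO without KO LPS 2 and 3 (−0.45), and Cenpe for the interaction with log2(FPKM + 1), filtered or not (0.0493 each), and log2(FPKM + 0.1) (0.0258).

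Libraries with the same replicate number did not deviate together (correlations of −0.63 to 0.57 over 18 pairs, median 0.09, 8 above 0.1), so the numbers were not taken to pair them. With the replicate number as a block, the counts were 2898, 3164, 2139, 3620 and 5285 and the glycolytic list had an adjusted p of 0.0834 (camera, Benjamini-Hochberg); no count moved by over 1.5 times. The 2 code numbers shared by 4 WT libraries gave correlations of 0.593 and 0.456, and libraries of one code were of the same sex. With the code as a block those 4 gave 1490 genes for the LPS effect in WT. Without the block edgeR called 0, with 1565 at an unadjusted p under 0.05, and no other tool was run on them. The blocked fit has 4 libraries for 2 groups and 2 codes, which leaves very little to estimate the spread. The rise in calls thus does not show that the code pairs libraries.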

Other observations

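In this part, the comparisons across both label columns, the test of sex and the relation with LPS-induced genes were chosen only after the results had been seen; the tests of HIF-1 target genes and of depth, and the splits for the glycolytic list, had been chosen before. Set against WT medium, neutrophil and B cell transcripts were higher as lists in the libraries labelled KO LPS, by way of KO LPS 2 and 3, while KO LPS 1 lay within the range of WT medium for the genes given here. Of 14 neutrophil and granule markers 11 were higher when adjusted over the list alone, with a median log2 fold of 2.49, and all 8 B cell markers were, with a median of 2.45 (camera, Benjamini-Hochberg adjusted p = 5.4e-08 and 2.4e-07, each with adjusted p = 0.533 with an estimated correlation). None of these passed over all genes. Mpo stood at 13.001, 308 and 716 CPM in the libraries labelled KO LPS 1 to 3 and at 45.7, 5.66 and 46.3 CPM in WT medium. Ngp, a granule protein, stood at 184, 1382 and 1680 CPM in the same libraries labelled KO LPS and at 178, 111 and 273 CPM in WT medium. Ighm, the immunoglobulin M heavy chain, stood at 44.1, 229 and 331 CPM against 68.9, 20.2 and 102 CPM. Markers of dendritic cells (2 higher of 10) and of mast cells and basophils (3 of 8), adjusted over the list alone, passed camera as well (Benjamini-Hochberg adjusted p = 0.0028 and 0.0081, with adjusted p = 0.562 and 0.791 with an estimated correlation). So did lists other than cell markers, with no member past the threshold: the ATF4 response (median 0.48), alternative activation (0.55) and, lower, mitochondrial mRNAs (−0.59), with camera Benjamini-Hochberg adjusted p = 9.7e-04, 0.0485 and 0.0177 and adjusted p = 0.252, 0.709 and 0.791 with an estimated correlation. The inflammatory lists did not differ past the threshold, with medians of −0.20 for LPS-induced genes and −0.02 for interferon-stimulated genes (camera, Benjamini-Hochberg adjusted p = 0.240 and 0.973). Adjusted over the list alone, 2 of the 32 LPS-induced genes were higher, with folds of the list from −2.65 to 3.86, and 0 of the 40 interferon-stimulated genes differed.

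Between the libraries labelled KO medium and WT LPS, ribosomal protein genes (median log2 0.91 over 55) and the nuclear-encoded respiratory chain (0.71 over 60) were higher in the former as lists (camera, Benjamini-Hochberg adjusted p = 2.8e-22 and 5.5e-15, each with adjusted p = 0.627 with an estimated correlation), with no single member past edgeR's threshold. LPS-induced genes had a median of 0.21 and HIF-1 target genes of −0.21 (camera, Benjamini-Hochberg adjusted p = 0.0092 and 0.0223, with adjusted p = 0.656 and 0.627 with an estimated correlation). The share of ribosomal protein genes overlapped between the groups, with 3.30%, 5.08% and 1.98% in the libraries labelled KO medium 1 to 3 and 3.12%, 1.18% and 2.01% in WT LPS. Cholesterol synthesis (0.49), the tricarboxylic acid cycle (0.25) and mitochondrial mRNAs (0.38) passed as higher (camera, Benjamini-Hochberg adjusted p = 5.4e-04, 0.0223 and 0.0223, with adjusted p = 0.643, 0.627 and 0.627 with an estimated correlation). Sex-linked genes passed too (camera, Benjamini-Hochberg adjusted p = 0.0229, and adjusted p = 0.627 with an estimated correlation), but with a median of 0.46 and a mean of −1.51, for 3 male libraries against 2 male and 1 female. The glycolytic enzymes had a median of −0.05 (camera, Benjamini-Hochberg adjusted p = 0.863). Over all genes edgeR called 0 here, with 270 at an unadjusted p under 0.05, where 688.7 are due by chance. With 1 library left out, the number at an unadjusted p under 0.05 ran from 87 (without WT LPS 2) to 1219 (without WT LPS 1). It thus depends on single libraries. DESeq2 called 1, limma-voom 0, edgeR 3 without the low-count filter and 2 without KO medium 1. For the libraries labelled KO LPS against WT medium edgeR called 0, with 1135 at an unadjusted p under 0.05, where again 688.7 are due by chance. With 1 library left out, that number ran from 352 (without KO LPS 3) to 2642 (without KO LPS 1). DESeq2 called 37, of which 35 were higher and 2 lower in the libraries labelled KO LPS. It made 31 false calls on data simulated for another contrast, the genotype effect in LPS, so how many of the 37 are false is not known. Calls by limma-voom were 0, and by limma-trend on unfiltered log2(FPKM + 1) 9 (5 higher and 4 lower). EdgeR called 99 without the low-count filter (95 higher and 4 lower) and 245 without KO LPS 1 (140 higher and 105 lower). For each of these comparisons the 10 splits of the libraries are no test, since the real one gave 0 calls and so did the highest other. By rank correlation over genes, the most similar library lay in another labelled group for 7 of the 12 libraries. For each of these 7 it lay in the group that differs in both genotype and treatment label. WT LPS 1 to 3 were nearest to libraries labelled KO medium, and those labelled KO medium 1 and 3 to WT LPS. The library labelled KO LPS 1 and WT medium 2 were nearest to each other. The first components of the log2 CPM, scaled here by the TMM factors, held 56.8% and 19.4% of the variance.

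The glycolytic enzymes differed between libraries of 1 labelled group, with mean log2 CPM of 7.14, 6.53 and 6.61 in the libraries labelled KO LPS and 6.39, 7.03 and 6.52 in WT medium. For the genotype effect in LPS, where the list's adjusted p was 0.0846 (camera, Benjamini-Hochberg), 4 of the 10 splits of the 6 libraries gave as small a value, the smallest of the others 0.0046, and 10 splits are too few for a share under 0.05. Over deviations from the group means of the 12 libraries, 3 relations were computed with exact permutation within groups. With HIF-1 target genes other than the glycolytic enzymes Pearson r was 0.18 (p = 0.559, adjusted 0.559 by Benjamini-Hochberg) and Spearman rho 0.0839 (p = 0.818, adjusted 0.818), and r was 0.256 without the 2 farthest libraries. An r under 0.3 had been set beforehand as counting against HIF-1, but the 95% interval of −0.55 to 0.75 is too wide to decide it, so HIF-1 activity that differs between cultures may still be a source. With depth r was −0.534 (95% interval −0.88 to 0.20; p = 0.120, adjusted 0.196 by Benjamini-Hochberg), rho −0.615 (p = 0.0741, adjusted 0.133) and r −0.449 without the 2 farthest, which leaves depth open. With LPS-induced genes r was 0.427 (−0.33 to 0.85; p = 0.130, adjusted 0.196 by Benjamini-Hochberg), rho 0.504 (p = 0.0887, adjusted 0.133) and r 0.755 without the 2 farthest. Sex could contribute, with males above females by 0.105 in WT LPS, 0.573 in the libraries labelled KO LPS and 0.574 in WT medium (log2). In WT LPS the TMM factors were 0.765, 1.02 and 0.819 for libraries 1 to 3, and library 2 was the female one. The sign there may thus depend on the scaling, and the differences were not computed without it. Each group with both sexes held 1 library of one of them. Sex and these explanations cannot be told apart with 12 libraries.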
